A study of Pseudomonas fluorescens with 2 samples.

How the data were processed

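RNA was sequenced from 2 deletion mutants of Pseudomonas fluorescens SBW25, labelled as lacking cbrB or ntrC. Both were grown in M9 minimal salts with 20 mM succinate and 10 mM histidine and taken in exponential growth, per the labels. The labels mention triplicate cultures, and each mutant has 1 library and 1 table. Whether the cultures were pooled is not given in the sources used here, and neither are the aligner, the counting tool, the normalization method and the genome build. The wild type and a hutC mutant were sequenced in parallel, per the design text of the series, and belong to another series. They are not analysed here as samples. The 2 tables hold 2 further columns of per-sample values, 1 in each table, which were not used. The wild type enters only through the authors' own comparison columns, and that it is the other library of each table rests on the design text.

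Each table lists 5921 genes in the same order, with locus tag, product and position, and 1058 of them have a gene symbol. Genes without a symbol are named by locus tag and by the product the table gives. Positions are those of the authors' tables. Expression is given as normalized TPM per the file headers, a signal that the authors rescaled within each table, so that the columns add up to 1167973 and 1184461, and the 2 tables were normalized separately. The log2 ratio of mutant over wild type was computed by the authors and deposited to 1 decimal. For the cbrB mutant it is a score rather than a plain logarithm, because 8 genes listed at 0 hold a placeholder deposited by the authors in place of minus infinity. These 8 genes were counted as lower, and no fold is given for them. The sign was read from these genes, which are at 0 in the mutant column and hold the most negative value. The p-value deposited by the authors is unadjusted and compares the 2 libraries of a table, and it is written as 0 where it was too small to print (123 genes for the cbrB and 212 for the ntrC mutant). A confidence score deposited by the authors repeats the p-value as a signed minus log10 and was not used for calls, and the signed ratio column repeats the log2 ratio.

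The depth in reads is unknown, because normalized TPM keeps no depth, so no counting interval is given and no count model was fitted. Genes with near-identical copies, such as transposases, share reads in a way that these tables do not show, and their values are uncertain. Whether counting used the strand is not given in the sources used here.

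The design was fixed before the data were examined. It allowed for counts per culture, and since the files hold 1 value per gene and mutant, its rule for that case was used. For each mutant against wild type, genes at the authors' p under 0.05 were counted by direction, without a fold threshold and with an absolute log2 ratio of at least 1. A gene is called higher or lower where it passes both. Overlaps of calls were compared with the number for independent lists (n1 × n2 / N), and an exact test per direction was computed but is not quoted, since genes are not replicates. Shared-control chance was simulated with 50 sets of 3 unchanged libraries at assumed depths of 1000000, 3000000 and 10000000 reads. This covers counting noise only. For the mutants against each other, log2((cbrB + 1) / (ntrC + 1)) was taken with a pseudocount of 1, without a test, and genes were counted at an absolute value of at least 1 among the 2961 genes at or above the median mean level.

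A total of 21 gene lists were fixed before the data were examined, by patterns on symbol or product text. For each list, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from the same 20 bins of mean expression over the 2 mutants (seed 7). Ties counted at 0.5, and a list outside the 2.5th to 97.5th percentile is described as above or below the range. This describes these libraries and is not a test of the conditions. Within lists, the authors' p was also adjusted by Benjamini-Hochberg over the list alone and over all genes. The list meant for ribosomal and transfer RNA matched 23 modification enzymes and no RNA gene, so it says nothing of RNA quality. It had 0 called members in the cbrB library (percentile 80.76) and 1 higher and 2 lower in the ntrC library (percentile 18.36). Between the mutants it was at percentile 85.25, and at 98.4 for the 15 members at or above the median level. The patterns also missed genes. The nitrogen list missed the ammonium transporter gene PFLU5952, the nitrate list the nitrate-binding protein gene PFLU4607 and the respiration list 12 NADH dehydrogenase genes. The misses were noticed after seeing the data, and 8 lists were recomputed with missed members found by product text whatever their values. The pattern for sugar genes was narrowed once, after it had brought in lipid A enzymes. The other lists may miss members too.

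The named genes follow a rule fixed before the data were examined. It takes cbrB, cbrA, ntrC, ntrB, hutC, crc and the glutamine synthetase type nitrogen genes, the 15 largest absolute log2 ratios per direction in each comparison, and up to 4 members per list past the same thresholds. No gene is named crc. The regulator gene hutC had log2 ratios of -0.3 and 0.2 in the authors' deposited table. PFLU5236, PFLU5237, PFLU5952, the neighbours in the hut region, the other regions of the closing section and the examples of genes with opposite calls were chosen after their values were seen.

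Alternatives fixed beforehand were other thresholds on p and fold, filters on level, an adjustment of the deposited p, other pseudocounts, a median-ratio scaling, random lists not matched on level, members by symbol alone and members at or above the median level. Added after seeing the data were centring on genes at or above the median level, centring on genes of like level in the other mutant (20 bins), the overlap among genes at or above the median level, the difference of the deposited log2 ratios, an added background, lists without members matched in error, lists with missed members included, and the nitrogen list and its tests without glnG, the gene deleted in the ntrC mutant. The steps were tested on simulated data for the 5921 genes. Of 100 lists of 20 genes, with noise independent between genes, 3 were outside the range with no shift, 85 with a log2 shift of 0.5 and 100 with a shift of 1. With 100 planted shared genes the mean excess over independent lists was 80.3, and with 0 it was -0.7. A planted trend with level, with a range of 2, was recovered with errors of at most 0.04. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.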

Results

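RNA sequencing measured the transcripts of Pseudomonas fluorescens SBW25, a plant-associated soil bacterium, in 2 deletion mutants. The strain labelled as the cbrB mutant lacks, by its label, the response regulator of CbrAB, a sensor kinase and regulator pair that controls the use of many carbon and nitrogen sources. The strain labelled as the ntrC mutant lacks the response regulator of NtrBC, the pair that switches on nitrogen scavenging genes. Both were grown exponentially in minimal medium with 20 mM succinate and 10 mM histidine, an amino acid that can serve as carbon and as nitrogen source. The labels speak of 3 cultures per strain, but each mutant is represented by 1 library with 1 value per gene, so no difference described here has a replicate check. Each library holds 5921 genes. Total normalized TPM (a transcript abundance scaled for length and library size, then rescaled by the authors) was 1167973 in the cbrB library and 1184461 in the ntrC library, and the 10 most abundant transcripts made up 18.6% and 16.6% of these totals. The depth in reads is unknown. In both libraries the most abundant transcript was PFLU4612, a putative outer membrane porin, at 50266.6 and 45472.9 normalized TPM.

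The deleted genes were examined before anything else, as a check of the labels. The gene for NtrC is listed as glnG (PFLU0343, positions 374209 to 375645, reverse strand). It stood at 1.4 normalized TPM in the ntrC library and at 204.3 in the cbrB library, with log2 ratios to wild type of -5.0 and 2.1 in the authors' deposited table. Its neighbour glnL (PFLU0344), which encodes the partner kinase NtrB, was present in both libraries at 73.1 and 119.4 normalized TPM. No gene carries the name cbrB or cbrA in the annotation used here, so the label of the cbrB library was not checked by a gene of that name. The sensor kinase gene PFLU5236 and the response regulator gene PFLU5237 (5745440 to 5746870, forward strand) lie side by side where background knowledge of this strain, not the annotation, places cbrA and cbrB. PFLU5237 was chosen for mention after its value was seen. It stood at 81.5 normalized TPM in the cbrB library and 209.4 in the ntrC library, with ratios to wild type of -1.4 and 0.0 on the log2 scale in the authors' deposited table, so transcripts assigned to it were fewer in the cbrB library but not absent. The libraries are named by their labels throughout.

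The comparison of the cbrB mutant with wild type asks which genes depend on CbrAB in this medium. Of 20 genes for nitrogen regulation and assimilation 7 were called higher in the cbrB library and 13 were not called, and of the 3 members of the nitrate list none was called. That list missed the nitrate-binding protein gene PFLU4607, which was called higher at 2.0 by the authors' deposited table. The nitrogen list lay above random lists of like level, but not without glnG (percentile 97.15) or among its 15 members at or above the median level (91.84). It stayed above them with members found by symbol alone (100) and with missed members included (99.79). Of the 7, PFLU4443 at 1.1 in the authors' deposited table was matched by product text and lies near the flagellar gene fliS. In the authors' deposited table the log2 ratio was 2.3 for glnA, which encodes glutamine synthetase, 2.0 for glnK, which encodes a PII signalling protein, and 2.7 for the ammonium transporter gene PFLU5952. Urease accessory genes rose as well, with 2.6 for ureE, 2.0 for PFLU0562 and 1.7 for ureG in the authors' deposited table. Of 44 genes of sugar and polyol use 13 were called lower, among them xylA, encoding xylose isomerase, at -3.6, fruK, encoding 1-phosphofructokinase, at -2.7, and the mannitol-binding protein gene PFLU2745 at -2.5 in the authors' deposited table. These 3 stood at only 2.1, 3.7 and 4.9 normalized TPM in the cbrB library, and the list no longer lay below random lists among its 16 members at or above the median level. No gene for breakdown of histidine itself was called. In the authors' deposited table hutU, encoding urocanate hydratase, had a log2 ratio of -0.2, hutH, encoding histidine ammonia-lyase, -0.1, the imidazolonepropionase gene PFLU0369 -0.5 (p = 8.6e-07), and the formiminoglutamate deiminase gene PFLU0358 and the hydrolase gene PFLU0370 -0.6 each.

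With the authors' unadjusted p under 0.05 and an absolute log2 ratio of at least 1, 434 genes were higher and 503 lower in the cbrB library by the authors' deposited table, out of 5921. Without the fold threshold the counts were 1162 higher and 665 lower. The p-values of the authors compare 2 libraries, not 2 conditions. Of the genes called lower, 454 lay below the median expression level, against 59 of those called higher, and 8 of those called lower are listed at 0 in the cbrB library. Among genes at or above the median level the split was 375 higher and 49 lower. That level is the mean of the 2 mutant libraries. A fall in the cbrB library lowers it and a rise lifts it, so part of this split is set by the filter. The deposited ratios were centred near 0 over all genes, while genes at or above the median level had a median of 0.3 in both comparisons with wild type. Taking that 0.3 off, a choice made after seeing the data, left 231 genes higher and 569 lower, so 28.9% instead of 46.3% of the called genes were higher.

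**Figure D1:**
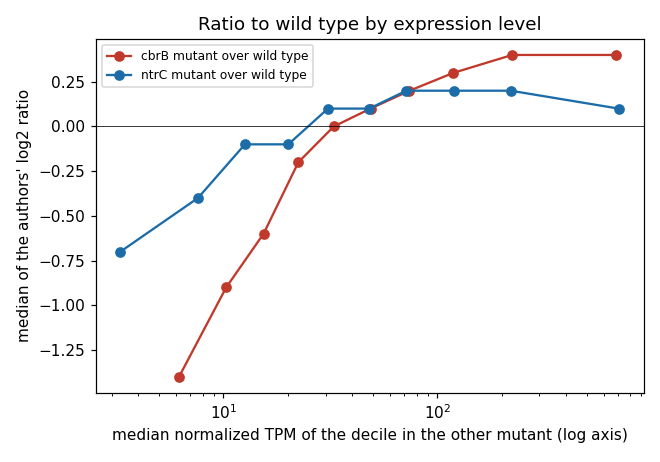
Median log2 ratio to wild type, by the authors' deposited table, in 10 equal groups of genes ordered by normalized TPM in the other mutant (horizontal, log axis), for the cbrB (red) and ntrC (blue) library. The medians go from -1.4 to 0.4 in the cbrB and from -0.7 to 0.1 in the ntrC library between the lowest and the highest group.

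The largest rises in the authors' deposited table were in PFLU3241, a hypothetical protein gene, at 5.5, in the putative endoribonuclease gene PFLU4272 at 4.0, and in PFLU1435 and its neighbour phaG, a transacylase gene of polyhydroxyalkanoate synthesis, at 3.5 and 3.3. They were followed by transporter genes, with PFLU5903 at 3.0 and the amino acid ABC transporter gene PFLU0588 at 2.9. The rise of PFLU1907, a hypothetical protein gene at 3.6 and only 9.7 normalized TPM in the cbrB library, no longer passed at p under 0.01. The hypothetical protein genes PFLU4872, PFLU3396, PFLU3398, PFLU3765 and PFLU3765A had log2 ratios between 2.5 and 2.8 in the authors' deposited table. The largest falls were mostly in transcripts under 2 normalized TPM, such as the ABC transporter gene PFLU3744 at -6.7 and phnH, of the carbon-phosphorus lyase, at -4.4 in the authors' deposited table. PFLU2583, encoding a putative rhizopine-binding protein, fell from a higher level, with a log2 ratio of -4.4 and 41.9 normalized TPM in the ntrC library, and the hypothetical protein gene PFLU1419 had -4.2 in the authors' deposited table.

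Of the 21 gene lists fixed before the data were examined, 5 had a median log2 ratio above the 97.5th percentile of random lists of like size and expression level in the cbrB library, and 4 lay below the 2.5th. Lists of genes that vary independently would give about 1.05 in all. Members of 1 operon can move together, so this number is not a chance rate for these lists. The nitrogen regulation list had 7 of 20 members higher and none lower (percentile 99.06), and the same 7 and 0 when the authors' p was adjusted over the list alone or over all genes. That percentile dropped to 91.84 among the 15 members at or above the median level, and to 97.15, inside the range, without glnG, 1 of the 7. The cbrB strain is not deleted for glnG. With members found by symbol alone it was 100, and against unmatched lists 99.82. It was 99.44 for the 18 members left without those matched in error, and 99.79 with missed members included (8 of 23 higher). Another of the 7, PFLU4443 at 1.1 in the authors' deposited table, was matched by product text and lies near the flagellar gene fliS. In the urea list 5 of 7 members were higher and 1 lower (percentile 99.99), the exception being ureB at -3.7 and 1.4 normalized TPM, by the authors' deposited table. Adjusted over the list alone 5 remained higher and over all genes 4. In purine, pyrimidine and allantoin catabolism 5 of 10 members were higher (percentile 99.96), led in the authors' deposited table by the cytosine deaminase gene codA at 2.1 and the phenylhydantoinase gene PFLU3942 at 1.5, with allA at 1.4 and the uricase gene PFLU4360 at 1.3. The count was 5 adjusted over the list alone and over all genes.

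Flagella and chemotaxis genes were also shifted upward in the cbrB library, with 22 of 120 members higher and 4 lower (percentile 100). Adjusted over the list alone 22 were higher and 2 lower, and over all genes 22 and 1. The flagellin gene PFLU4448 reached 10149.8 normalized TPM with a log2 ratio of 1.9 in the authors' deposited table, and the flagellin-like PFLU4447 had 1.6. In dicarboxylate uptake and the TCA cycle, the route by which succinate is oxidised, 6 of 32 members were higher and 2 lower (percentile 99.0), with 1.5 for mqo, PFLU1613, and for the isocitrate dehydrogenase gene PFLU3808 in the authors' deposited table. Adjusted over all genes 6 were higher and 0 lower, and with members found by symbol alone that list fell to percentile 95.98. In the sugar and polyol list 13 of 44 members were lower and 3 higher (percentile 1.86), with 9 lower adjusted over the list alone and 5 over all genes. This call was lost among the 16 members at or above the median level (percentile 30.62) and with members found by symbol alone (3.54). That level includes the cbrB value, so the filter can drop members that fell there. The list stayed below the range against unmatched lists (0.02) and with 8 missed members included (19 of 52 lower and 3 higher, percentile 1.06). Ribosomal protein genes (57 members, 3 higher) and respiration genes (32 members, none past the thresholds) had list medians of 0.2 and 0.05, which turn negative once the 0.3 is taken off and lay below those of genes of like level (percentiles 0.13 and 0.88). Their percentiles were 94.8 and 62.35 against random lists not matched on level. The respiration list missed 12 genes from PFLU3818 to PFLU3830 for subunits of NADH dehydrogenase, of which PFLU3824 and PFLU3825 were called higher at 1.0 and 1.4 by the authors' deposited table, and with missed members included it lay inside the range (2 of 45 higher, percentile 20.7). Iron uptake genes had a median of -0.3 with 0 of 53 members called (percentile 0.06). With members found by symbol alone the percentile was 12.55, and against unmatched lists 2.25. The matching uses the mean of the 2 mutants, which the ntrC library lifts for members such as fpvA (65.5 normalized TPM in the cbrB and 7044.5 in the ntrC library). Such members are set against genes of higher level than their own in the cbrB library, so part of the 0.06 may come from the matching.

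The remaining lists stayed inside the range of random lists in the cbrB library. Of 78 amino acid uptake genes 5 were higher and 7 lower, but 4 and 1 adjusted over the list alone and 5 and 1 over all genes. Of 32 genes for arginine and polyamine catabolism 4 were lower (3 adjusted over the list alone or over all genes), including the arginine succinyltransferase gene PFLU4755 at -2.1 in the authors' deposited table. In the list of proline, branched-chain and aromatic amino acid catabolism 2 of 16 members were lower, PFLU5203 at -1.8 and PFLU3964 at -1.4 by the authors' deposited table. Stress response had 5 of 53 members higher (percentile 50.15, and 99.12 against random lists not matched on level), with cold shock genes PFLU3807 at 2.0, cspA2 at 1.5 and cspA1 at 1.3 in the authors' deposited table. Surface polysaccharides had 2 of 32 higher, algA at 1.4 and algQ at 1.0 by the authors' deposited table. Secretion systems had 1 of 22 higher and 4 lower, with 1 lower adjusted over the list alone or over all genes (percentile 87.56, and 0.49 against unmatched lists). Prophage had 4 of 53 each way, with 0 lower adjusted over the list alone and 1 over all genes, and peptide uptake 1 of 15 higher. The lower prophage members include the choline transporter genes PFLU0249 at -1.5 and betT at -1.4 in the authors' deposited table, matched in error. The hut list (5 members) held no called gene. Its median was -0.2 in the authors' deposited table, against 0.3 for random lists of like level (percentile 2.97), and it lay below the range with its 4 members at or above the median level (0.73) and with 2 missed members included (0.93). Carbon repression regulators (4 members) held no called gene, and the nitrate list (3 members) none apart from PFLU4607, with which it went to percentile 98.68.

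The comparison of the ntrC mutant with wild type asks which genes depend on NtrBC. Of 53 genes of the iron uptake list 28 were called higher and 5 lower. The 5 include the bacterioferritin genes bfr1, PFLU0568 and bfr2 at -4.5, -2.5 and -2.4 in the authors' deposited table. These encode iron stores, not uptake. In the authors' deposited table pvdG, of pyoverdine synthesis, had a log2 ratio of 8.1, the ferripyoverdine receptor gene fpvA 7.1, the siderophore receptor gene PFLU2688 7.0 and the pyoverdine synthetase gene PFLU2547 6.8. The fpvA transcript went up to 7044.5 normalized TPM, against 65.5 in the cbrB library. Nitrogen genes went both ways. In the authors' deposited table gltB and gltD, encoding glutamate synthase, had -2.8 and -1.8, while gdhA, encoding glutamate dehydrogenase, had 1.2 and glnL 1.0. Also called higher was argA, but this list member, at 1.3 in the authors' deposited table, belongs to arginine synthesis and was matched in error. The pyrimidine catabolism genes PFLU3942 and PFLU3944 had -3.8 and -4.8, and the putrescine-binding protein gene PFLU2564, from a list with 7 members higher and 5 lower, -5.2 in the authors' deposited table. The histidine transporter genes PFLU0363, PFLU0364 and PFLU0365 and the histidine lyase gene PFLU0366 were called lower, at -2.0, -1.3, -1.8 and -1.4, whereas hutU at 0.5 and hutH at -0.7 were not called in the authors' deposited table.

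With the same thresholds 739 genes were higher and 484 lower in the ntrC library by the authors' deposited table, and 1233 and 891 without the fold threshold. At or above the median level the split was 603 higher and 167 lower, and part of it is again set by the filter, since the ntrC value enters that level. Centred on genes at or above the median level, 507 genes were higher and 648 lower, so the share of higher genes went from 60.4% to 43.9%. Next to the siderophore genes, large rises in the authors' deposited table were found in the heme-binding protein gene PFLU5359 at 5.8 and 22074.3 normalized TPM, the aminotransferase gene PFLU5135 at 7.7, the diaminobutyrate-2-oxoglutarate aminotransferase gene PFLU4378 at 6.9, the ornithine monooxygenase gene PFLU3975 at 6.6 and the peptide synthase gene PFLU6137 at 6.2. The hypothetical protein genes PFLU4377 and PFLU2548 had 7.2 and 6.5, and PFLU2546, PFLU2549 and PFLU3977 lay between 5.8 and 6.3 in the authors' deposited table. Large falls in the authors' deposited table included bfr1, encoding bacterioferritin, an iron store, at -4.5, the glutamine-binding protein gene PFLU4268 at -4.4 with its neighbours PFLU4267 and PFLU4269 at -4.2 each, PFLU1419 at -4.4 and the hydroxymethylglutaryl-CoA lyase gene PFLU1417 at -3.4.

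In the ntrC library 2 lists lay above and 3 below the range of random lists. Iron uptake had 28 of 53 members higher and 5 lower (percentile 100), with 28 higher and 4 lower adjusted over the list alone and over all genes. The median of these members was 1.2 in the authors' deposited table, while random lists of like level had 0.0. Stress response had 16 of 53 members higher and 3 lower (percentile 97.86), led in the authors' deposited table by the heat shock gene PFLU4295 at 4.6, the superoxide dismutase gene sodA and the chaperone gene htpG at 4.5 each, and dnaK at 3.5. Adjusted over the list alone and over all genes 16 were higher and 1 lower, but without members brought in by their product text in error the percentile was 94.22. In the urea list 3 of 7 members were lower and none higher (percentile 0.82), with ureE at -1.9 and ureG at -1.8 in the authors' deposited table. Respiration had 8 of 32 members lower and 1 higher (percentile 0.16), among them the cbb3 oxidase genes PFLU4556 at -2.8 and PFLU4555 at -2.6 and the NADH dehydrogenase gene PFLU3822 at -2.3 in the authors' deposited table. Against unmatched random lists this percentile was 11.64, with members found by symbol alone 3.0, and with missed members included, among them 10 NADH dehydrogenase genes called lower and 2 called higher, it was 0 (18 of 45 lower and 3 higher). Ribosomal protein genes had a median of -0.2 (percentile 0, and 6.75 against unmatched lists). The type B gene for L31, rpmE2, had a log2 ratio of 4.1, while rpmE had -1.1 in the authors' deposited table.

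The other lists had called members in both directions, in 1 direction only or none. Nitrogen regulation had 3 of 20 members higher and 4 lower (percentile 15.08), and 1 of the 4 is glnG, the deleted gene itself. Without it 3 of 19 were higher and 3 lower (percentile 25.31), with glnA at 0.6 and glnK at 0.3 in the authors' deposited table. Purine, pyrimidine and allantoin catabolism had 2 of 10 members lower (percentile 2.87), a value that went to 1.14 among the 9 members at or above the median level and to 0.92 with 5 missed members included. Of 78 amino acid uptake genes 2 were higher and 8 lower (3 lower adjusted over the list alone or over all genes), including PFLU0588 at -2.6, while the glutamate transporter gene gluA had 1.6 in the authors' deposited table. Arginine and polyamine catabolism had 7 of 32 members higher, such as PFLU4756 at 2.1 and PFLU4036 at 2.3 by the authors' deposited table, and 5 lower. The tyrosine breakdown genes PFLU1026, PFLU2997 and hmgA had -2.4, -2.0 and -1.4 in the authors' deposited table, in a list with 3 of 16 lower and 2 higher. Sugar genes had 5 of 44 higher, led by the glucose dehydrogenase gene gcd at 3.0, and 6 lower by the authors' deposited table (5 adjusted over the list alone or over all genes). In dicarboxylate uptake and the TCA cycle 6 of 32 members were higher, with fumC at 5.2, and 2 lower, with the dicarboxylate transporter gene PFLU4717 at -1.8 in the authors' deposited table. The cellulose synthase gene wssB had -1.9 and wssC -1.6 in the authors' deposited table, among 9 of 32 surface polysaccharide genes that were lower (8 adjusted over the list alone or over all genes). The prophage list had 15 of 53 higher and 1 lower (percentile 97.36, and 99.54 among the 25 members at or above the median level), or 14 and 0 adjusted over the list alone or over all genes. The 15 include the choline transporter gene opuBA at 1.0 and the phospholipase gene plc at 1.8 in the authors' deposited table, both matched in error. Without such members the percentile was 97. Flagella had 10 of 120 higher and 4 lower. Peptide uptake had 3 of 15 higher, secretion systems 4 of 22 lower (2 adjusted over the list alone or over all genes, percentile 45.46, and 1.24 against unmatched lists), and carbon repression regulators 1 of 4 higher, the hfq gene at 1.4 by the authors' deposited table. The hut and nitrate lists held no called gene, but both missed members called lower by the authors' deposited table, PFLU0366 at -1.4 and PFLU4607 at -1.6, and with PFLU4607 the nitrate list went to percentile 1.48.

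**Figure D2:**
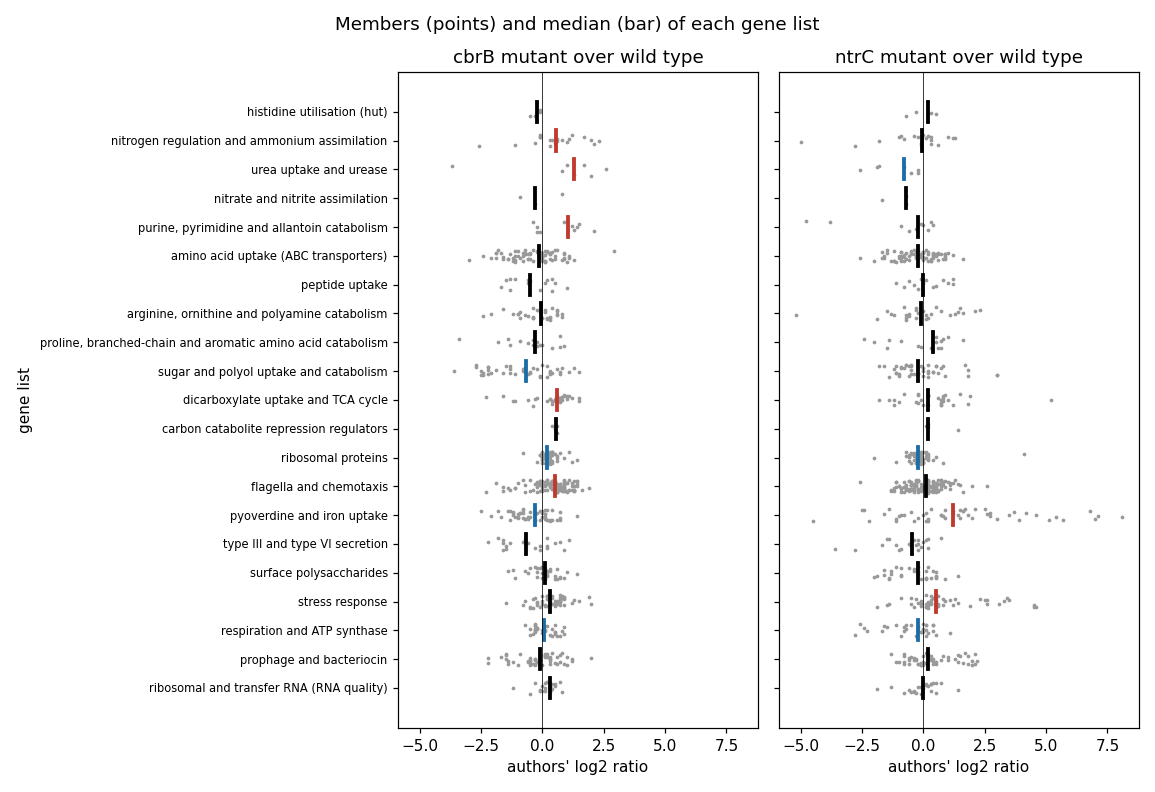
Log2 ratio to wild type of each member (grey points) of the 21 gene lists in the cbrB (left) and ntrC (right) libraries, by the authors' deposited table, with the list median as a bar, red above the 97.5th and blue below the 2.5th percentile of 10000 matched random lists, black otherwise. Members listed at 0 are left out, and the iron uptake list stands out on the right with a median of 1.2.

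Whether the same genes respond to both deletions was asked by overlapping the calls. Both tables use the same wild type, so part of any overlap may come from it, and with 1 wild-type library the controls cannot be split. Among 5921 genes, 150 were higher in both libraries, against 54.2 for independent lists, and 170 were lower in both, against 41.1. At or above the median level these counts were 138 against 76.4 and 11 against 2.8. Centred on genes of like level they were 68 against 28.6 and 72 against 33.4, so part of the excess goes with level. In simulated unchanged libraries sharing a control, with counting noise alone and an assumed 1000000 reads, 11.4 genes were higher in both and 6.6 lower in both. A simulated comparison called only 104.8 genes on average, against 937 and 1223 in the data. The simulated overlaps therefore do not bound the part that comes from the shared control. Opposite calls numbered 0.0 in the simulation, but noise in a shared control pushes calls to the same side. Opposite calls were found for 39 genes higher in the cbrB and lower in the ntrC library (35.5 for independent lists) and for 18 genes lower in the cbrB and higher in the ntrC library (62.8 for independent lists). The 39 genes included glnG, whose fall in the ntrC library is the deletion itself, and phaG, ureE, ureG, gltD, PFLU0588, PFLU3942 and 6 neighbouring genes from PFLU4265 to PFLU4270. The 18 genes included thiC of thiamine synthesis, the pectin lyase gene pnl and the peptide synthetase gene PFLU3222. Among genes at or above the median level the count of 39 became 36, against 21.1 for independent lists, and the count of 18 became 15, against 10.0. That level is the mean of the 2 mutants, so a high value in 1 library can carry a gene over it. An example is PFLU3978, at 1.9 in the cbrB and 162.0 normalized TPM in the ntrC library. The change from a deficit to an excess for the 18 is thus partly set by the filter. The count of 18 stayed a deficit when centred on genes of like level (23 against 39.3) and at p under 0.01 (12 against 28.3). The count of 39 became an excess at a like level (49 against 24.4), at p under 0.01 (36 against 23.3) and at a log2 of at least 2 (7 against 1.1). Without a fold threshold it stayed near independence (177 against 174.9). Centring uses the level in the other mutant, which can itself push opposite ratios further apart.

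Setting the 2 mutant libraries directly against each other avoids the wild type but crosses 2 tables that the authors normalized separately. At or above the median mean level of 41.4 normalized TPM (2961 genes), 305 genes were at least 2-fold higher in the cbrB library and 357 lower, on the log2(value + 1) scale. After median-ratio scaling the balance turned to 361 higher and 329 lower. No test was made, since each strain has 1 library. The highest in the cbrB library were PFLU4268 (2115.4 against 22.4 normalized TPM, log2 ratio 6.50), glnG (6.42), PFLU4269 (6.42), PFLU4267 (6.21), PFLU3944 (5.64) and PFLU0588 (5.42). The lowest were PFLU4378 (5.1 against 1843.3 normalized TPM, log2 ratio -8.24), PFLU2548 (-7.43), PFLU4377 (-7.40), PFLU2688 (-7.24), PFLU5135 (-7.22) and PFLU6137 (-7.11). The dipeptidase gene PFLU2550 and the peptide synthase gene pvdI had -6.93 and -6.24.

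Between the libraries 7 of the 21 lists lay above and 3 below the range of random lists. The nitrogen regulation (7 of 20 higher in the cbrB library, 1 lower, with the deleted glnG 1 of the 7), urea (4 of 7 higher) and purine, pyrimidine and allantoin (6 of 10 higher) lists were at percentiles 99.96, 100 and 100, and the first at 99.83 without glnG. The 7 also include PFLU4443, at 609.7 against 298.0 normalized TPM. Without members matched in error the nitrogen list was at 99.97. Surface polysaccharides had 7 of 32 higher (percentile 99.99), with wssB at a log2 ratio of 1.86. Flagella and chemotaxis had 19 of 120 higher and 1 lower (percentile 100), led by the chemotaxis receptor genes PFLU2358 at 2.65 and PFLU1687 at 2.55, but the 32 members found by symbol alone were at percentile 71.26. Ribosomal proteins had 3 of 57 higher and 1 lower (percentile 99.4), and secretion systems no called member (percentile 99.6, 80.88 unmatched, and 93.68 for the 3 members at or above the median level). Iron uptake had 24 of 53 members lower in the cbrB library and 3 higher, among the 3 the iron store gene bfr1 (percentile 0). Prophage had 10 of 53 lower and 1 higher (percentile 1.18, and 3.08 without members brought in by their product text in error). Proline, branched-chain and aromatic amino acid catabolism had 3 of 16 each way (percentile 0.61, 13.76 by symbol alone, and 9.99 for the 8 members at or above the median level). The 53 stress genes had 13 lower and 3 higher (percentile 36.56), with sodA at -4.01 and htpG at -3.60, and the 18 members found by symbol alone lay below the range at percentile 0. Sugar and polyol genes had 4 of 44 lower and 2 higher (percentile 11.79, but 0.13 for the 9 members found by symbol alone, 1.52 unmatched and 0.02 with 8 missed members included), and amino acid uptake genes 7 of 78 higher and 2 lower (percentile 10.47, and 1.38 unmatched). With missed members included the respiration list lay above the range (16 of 45 higher, percentile 100), and so did the nitrate list with PFLU4607 (99.98).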

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

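All explanatory tests in this part were chosen after the results were seen, and with 1 library per mutant no difference between the mutants was tested against replicates. A difference between the groups drew attention to the genes called in opposite directions against wild type, 39 higher in the cbrB and lower in the ntrC library (38 without the deleted gene glnG) and 18 the other way round. Apart from exact tests of these overlaps against independent lists, which take genes as replicates and are not quoted, that difference was not tested. For the urea list the percentile among matched random lists was 99.99 in the cbrB library and 0.82 in the ntrC library, and for iron uptake it was 0.06 and 100. These differences were not tested either. Part of the 0.06 may come from matching on a mean level that the ntrC library lifts, and against unmatched lists it was 2.25. The wild-type test of the nitrogen, urea and nucleobase genes below is the second that was tried. The first asked whether the cbrB library stood above the ntrC library over all 37 members, gave a median log2 ratio of 1.03 (0.18 to 1.69 over resampled members) and was read as undecided. It was replaced after its result was seen, because that ratio leaves out the wild type, and the second does not decide the question either.

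Iron uptake genes were higher in the ntrC library, with 28 of 53 members called. A scaling error of the size of the 0.3 centred off does not account for it, since 26 of the 28 stayed past the fold threshold. The deposited p was kept, so only members just past the fold threshold could be lost. A shift common to all genes would also leave the gap between the list median of 1.2 and the 0.0 of random lists of like level. A wild-type library low in these transcripts is argued against by the comparison that leaves the wild type out, where the median log2 ratio of cbrB over ntrC was -1.29 over all 53 members (-1.94 to -0.88 over resampled members), unless loss of CbrB lowered them as much. What stays open is whether loss of NtrC or less metal available to the 1 ntrC culture or pool raised these genes, and these cannot be told apart with 1 ntrC library. The rise of rpmE2 and sodA and the fall of bfr1, which are known to respond to zinc or iron supply in related bacteria, go with either. Of these genes, bfr1 is itself a member of the iron uptake list.

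Genes of low level were lower in the cbrB library, with a median log2 ratio to wild type of -1.4 in the lowest of 10 groups by level in the ntrC library and 0.4 in the highest, in the authors' deposited table. Background reads in the wild-type library alone would leave the low ends of both mutant libraries equal, yet the 10th percentile of the cbrB library was 0.66 of that of the ntrC library (0.62 to 0.69 over resampled genes). Background reads spread over all genes, fewer in the cbrB library, may be part of it, since the gap between the libraries at the 1st, 2nd, 5th, 10th and 20th percentiles stayed between 2.3 and 2.9 normalized TPM, a largest over smallest gap of 1.26. The gap was not constant further up, at 1.6 at the median and -9.0 at the 90th percentile. Loss of CbrB stays open as well, with 1 cbrB library. The ntrC library had a weaker trend the same way, from -0.7 in the lowest to 0.1 in the highest group by level in the cbrB library. A part that comes from the shared wild-type library thus stays open too. The low genes called lower carry these doubts, 454 in the cbrB and 317 in the ntrC library.

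Genes of the nitrogen, urea and nucleobase lists were higher in the cbrB library than in wild type, 17 of 37 of them called. Among the 17 is PFLU4443, which was matched by product text and lies near the flagellar gene fliS. A wild-type library low in the genes of these lists stays open, with 1 wild-type library. The 17 had a median log2 ratio of -0.5 (-1.8 to 0.0 over resampled members) in the ntrC library in the authors' deposited table, and without glnG -0.35 (-1.2 to 0.0). Their medians in the cbrB library, 1.5 and 1.45 without glnG, are set by the selection, since the 17 were picked for a ratio of at least 1 there. The ntrC values do not decide the question, since loss of NtrC may lower these genes and mask a low wild type. After centring on genes of like level in the ntrC library, 14 of the 17 stayed past the fold threshold (13 of 16 without glnG). The deposited p was kept, so only the fold threshold could be lost. Some of these genes were low in the ntrC library, such as ureE at 14.2 normalized TPM. At low levels there the median ratio was negative, so centring raises the ratios of such genes. This test thus cannot decide how much of the pattern comes from the trend with level. NtrC raising these genes in the cbrB mutant stays open too. Of the 17, 12 lay below wild type in the ntrC library, but 1 of these is glnG, whose fall is the deletion itself. Without it 11 of 16 lay below wild type and 5 were called lower there, against 11 below wild type of the 20 other members (exact test, two-sided p = 0.5 with and without glnG). That test and the resampled intervals in this part take genes as replicates and do not measure the spread between libraries. Both ratios also share the wild-type library.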

How the results depend on the processing

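No paired analysis was possible because each mutant has 1 library, and for the same reason leaving out replicates and a replicate block were not run, nor were count normalizations, which need counts. Of 74 recomputed counts 40 stayed within 1.5 times the reported one. Centring on genes at or above the median level, centring at a like level, the level filter on overlaps, the difference of deposited ratios, the added background the lists without mismatched members or with missed members and the nitrogen list without the deleted gene were chosen after seeing the data. The cause was not tested except where fewer genes or a stricter threshold set the count. Of the changed counts, cbrB against wild type gave 242 lower at p under 0.01, 262 with Benjamini-Hochberg adjustment, 49 at or above the median level and 147 above the lower quartile. It gave 1162 higher with no fold threshold, 55 higher and 229 lower at an absolute log2 of at least 2, 231 higher when centred on genes at or above the median level and 278 when centred at a like level. For ntrC there were 1233 higher and 891 lower with no fold threshold, 242 and 116 at a log2 of at least 2, 167 lower at or above the median level and 278 above the lower quartile. Overlap counts without a fold threshold were 532 higher in both, 258 lower in both, 177 higher in cbrB and lower in ntrC and 51 the reverse. At a log2 of at least 2 they were 4, 32, 7 and 3. Lower in both became 79 at p under 0.01, 11 at or above the median level and 72 at a like level, where higher in both became 68. Between the mutants there were 466 higher and 909 lower with no floor, 562 higher with background added and no floor, 681 and 589 at 1.5-fold, and 90 and 176 at a log2 of at least 2. Of 228 recomputed list percentiles 191 kept their side of the range, a count that takes in lists inside the range both times. Against unmatched random lists ribosomal proteins went to 94.8 and respiration to 62.35 in the cbrB library. Of 1260 recomputed named-gene ratios 1151 kept their call, but 252 of these are at p under 0.1, where no call can be lost. The named genes were also largely picked for large ratios. The transposase gene PFLU5307 went from -1.5 to 0.1 in the cbrB library when centred at a like level. Depth is unknown, so its limit on low genes could not be given.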

Other observations

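The regions in this part were chosen after their values were seen. A run of 11 genes from PFLU4265 to PFLU4275 (4709563 to 4720031), with a glutamine-binding protein, a transporter ATPase and a LysR-type regulator among its products, had all 11 members called higher in the cbrB library and 7 called lower in the ntrC library. The log2 ratios in the authors' deposited table ran from 1.1 to 4.0 in the cbrB and from -4.4 to -0.2 in the ntrC library. The 5 genes from PFLU3940 to PFLU3944, with a phenylhydantoinase and a dihydropyrimidine dehydrogenase that break down pyrimidines, were all called lower in the ntrC library, and 3 of them higher in the cbrB library. In the hut region from PFLU0358 to PFLU0370 (13 genes), none was called in the cbrB library, whereas 4 were called lower and 1 higher in the ntrC library. The 4 were the transporter genes PFLU0363, PFLU0364 and PFLU0365 and the histidine lyase gene PFLU0366, with -1.4 for the last in the authors' deposited table.

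In the ntrC library all 11 genes from PFLU6085 to PFLU6094 were called higher, with log2 ratios of 1.7 to 6.0 in the authors' deposited table, and 1 of them, PFLU6090 at -1.5, was called lower in the cbrB library. They encode a cation ABC transporter, a cobalamin synthesis-like protein and further copies of hisI and of a dihydroorotase gene that the annotation also lists elsewhere. The phage tail region from PFLU1171 to PFLU1185 had 14 of 15 genes called higher in the ntrC and 3 lower in the cbrB library, and the cytochrome oxidase region from PFLU4554 to PFLU4560 had all 6 genes lower in the ntrC library and none called in the cbrB library.

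Of the 150 genes higher in both libraries 91 (60.7%) encode hypothetical proteins, against 32.8% of all genes, and their median length was 522 bases against 870 bases for all genes. The hypothetical protein genes PFLU3241 and PFLU1419 moved alike in both libraries, with 5.5 and 5.0 for PFLU3241 and -4.2 and -4.4 for PFLU1419 in the authors' deposited table. Of the 170 genes lower in both, 159 lay below the median level, against 12 of the 150 higher in both. That level is the mean of the same 2 libraries, so these counts are partly set by the selection.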
